A study of Mus musculus with 8 samples.

How the data were processed

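The series profiled the genome occupancy of Runx1, a Runt-domain transcription factor of blood cell development, by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse C57BL6/J early T cells. Per the labels' protocols, lineage-negative bone marrow cells of Cas9 mice were cultured on OP9-DL1 stroma, a feeder line that presents the Notch ligand Delta-like 1, with IL-7 and Flt3L at 10 ng/ml each. DN1 cells (Kit+ CD25-) were sorted on day 5 and DN3 cells (Kit- CD25+) were harvested on day 14. Chromatin of 10000000 cells was fixed with DSG for 30 min and then with 1% formaldehyde for 10 min, and was precipitated with 5 µg of anti-Runx1 antibody. Reads were single and 50 nt long. There were 8 libraries: 2 Runx1 ChIP and 2 input libraries at each of the 2 stages.

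The deposited data were 1 peak list per stage, titled by the authors as HOMER peaks kept by IDR, a filter for peaks that rank alike in replicates. Each list was taken as the combined list of its stage, since no column names a replicate. Whether the listed tags come from pooled libraries is not given in the sources used here. Per the submitters' processing notes, Bowtie 1.1.1, HOMER, SAMtools and bedtools were used with the mouse build mm9. The IDR threshold, the HOMER version and the treatment of reads with several alignments are not given in the sources used here. In the deposited lists the tag count per peak is a raw count of whole tags. The authors' normalized tag count is a signal proportional to it, scaled to a fixed library total that the file headers leave out. One normalized unit was worth 6.94 tags in DN1 and 7.74 tags in DN3, within 1% for 100% and 97.4% of the peaks. The total of tags behind a list is proportional to this value if both lists had the same scale. The depth of single libraries is unknown. The deposited input signal is the input tag count scaled to the ChIP by the authors' peak caller. The authors' lists also give, per the file headers, a findPeaks score, a focus ratio (the fraction of a peak's tags placed around its centre as a point source would place them), the fold of ChIP over input, the fold over the local background and a clonal value. These scores and folds are the authors' own values for each peak and were used to rank and filter peaks within their own list. Medians of the 2 lists are printed beside each other as a description, without a test across stages. In both lists no peak had a normalized tag count under 15, a fold over input under 4.01 or a fold over local background under 4.

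Coordinates are printed as the files give them, in mm9. As a check of the build, positions on chromosome 7 were set against a RefSeq gene table of assembly GRCm38. There 129 DN1 and 164 DN3 peaks lay beyond the last gene, reaching 152470046 in DN1 and 152503793 in DN3. This goes with positions that are not in GRCm38, though peaks beyond the last gene do not by themselves settle the build. Coordinates were not converted between builds and the files hold no gene column. Gene assignment, promoter shares, the gene lists fixed for the tests and motif content were therefore not analysed here. The planned test on tags per library was not run, because the lists hold no column per library. No result compares replicates, and no p-value compares the stages across replicates.

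Before the data were examined, the overlap rule, its alternatives, the test of scores and the rule for named peaks were fixed. A peak was shared if it overlapped a peak of the other list by at least 1 bp, and otherwise was called DN1-only or DN3-only. These names say that a peak is missing from the other list, which is not a measurement of no binding. Chance overlap was the share of peaks that overlapped the other list after a move of 1 Mb to either side, leaving out peaks moved beyond the span of the other list. Intervals for shares are 95% Wilson intervals. They cover counting error only, and peaks are not independent replicates. The log2 scores of shared and stage-only peaks of 1 list were compared with a two-sided permutation test of the difference of medians with 100000 resamples, with Benjamini-Hochberg adjustment over the 2 lists, and intervals from 1000 bootstrap draws. The rule for named peaks took the 5 highest findPeaks scores among DN1-only, DN3-only and shared peaks (the last by DN1 and by DN3 score), with ties ordered by normalized tag count. Distances between peaks are from centre to centre.

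The alternatives fixed beforehand were peak centres within 100 bp or 1000 bp, a reciprocal overlap of 50%, the upper 50% of each list by score, lists of equal length and the upper 50% of one list against the whole other list. A move of 100 kb for chance overlap was planned too. Chosen after seeing the data were a move of 10 kb, the upper 10% of one list, other measures of strength, stage-only peaks over 1000 bp from the other list, and the removal of unplaced contigs, high-input peaks and twins. High input means scaled input of at least 10 times the list's median. Twins are peaks with the same tag count, scaled input, fold over input, focus ratio and clonal value as another peak of their list.

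The code was tested on simulated data. For the overlap of the stages, 50% of 10000 simulated peaks were placed on DN3 peaks and 50% were recovered as shared. For the DN1 scores of 21443 peaks, a planted log2 difference of 0.2 was recovered as 0.20. Both outcomes follow from how the simulated data were built, so they check the arithmetic of the code only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.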

Results

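Runx1 occupancy was profiled by ChIP-seq at 2 stages of T cell development in culture. DN1 cells (Kit+ CD25-, day 5) precede commitment to the T lineage and still express the factor PU.1, and DN3 cells (Kit- CD25+, day 14) are committed T cell precursors in which PU.1 has been silenced. The study's title places the data in the question of how PU.1 redirects its partner factors, Runx1 among them, between genomic sites. Each stage had 2 ChIP libraries, which the authors reduced to 1 list of reproducible peaks, and 2 input libraries. Stage and days in culture changed together, so a difference between the lists is one of both.

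Runx1 peaks were more numerous at the DN3 stage. The DN3 list held 33129 peaks and the DN1 list 21443, a ratio of 1.54. The DN3 list had more peaks on each of the 19 autosomes, with ratios between 1.36 on chromosome 7 and 1.86 on chromosome 18, and 1.89 times as many on the X chromosome (579 against 307). Nearly all peaks had one fixed width, 215 bp in DN1 and 275 bp in DN3, and the lists covered 4610 kb and 9110 kb. DN1 peaks held 5070201 ChIP tags with a mean of 236 per peak, and DN3 peaks held 14372210 with a mean of 434. If the normalized counts were scaled to 10000000 tags, HOMER's usual setting, 7.31% of the DN1 tags and 18.6% of the DN3 tags lay in peaks. The median peak was 21.2-fold over input and 12.2-fold over its local background in DN1, against 33.8-fold and 18.0-fold in DN3. The median scaled input under a peak was 9.8 tags in DN1 and 9.9 tags in DN3. These values are not directly comparable, since the peak widths differed and input was scaled to the ChIP of each list. With 1 list per stage, these numbers have no replicate error and no test.

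Most DN1 positions were also present in the DN3 list, while about as many DN3 peaks were DN3-only as shared. A set of 16352 peaks overlapped one-to-one between the lists. They made up 76.3% of the DN1 peaks (95% interval 75.7% to 76.8%) and 49.4% of the DN3 peaks (48.8% to 49.9%). The remaining 5091 DN1 peaks were DN1-only and 16777 DN3 peaks were DN3-only, which is 3.30 DN3-only peaks for each DN1-only peak. Because shared peaks match one-to-one, the excess of DN3-only over DN1-only peaks equals the difference in length of the lists. Of the 38220 distinct positions in the union, 42.8% were shared, 13.3% were DN1-only and 43.9% were DN3-only. Moved by 1 Mb, 1.05% of the DN1 peaks and 0.678% of the DN3 peaks overlapped the other list, so the observed overlap was 72.7 times the chance overlap for DN1. With moves of 100 kb and 10 kb it was 45.0 and 36.3 times the chance overlap. The centres of shared peaks lay a median of 25 bp apart (interquartile range 12 to 46 bp).

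DN1-only and DN3-only peaks differed in their distance from the other stage's sites. A DN1-only peak had its nearest DN3 peak at a median of 7.27 kb between centres, and 578 of 5091 DN1-only peaks (11.4%) had none within 50 kb. A DN3-only peak had its nearest DN1 peak at a median of 19.2 kb, and 4383 of 16777 (26.1%) had none within 50 kb. These distances depend on the number of peaks in the other list, which was larger for DN1-only peaks. Among the DN1-only peaks 775 (15.2%), and among the DN3-only peaks 782 (4.66%), had a peak of the other list within 1 kb without overlapping it.

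**Figure D1:**
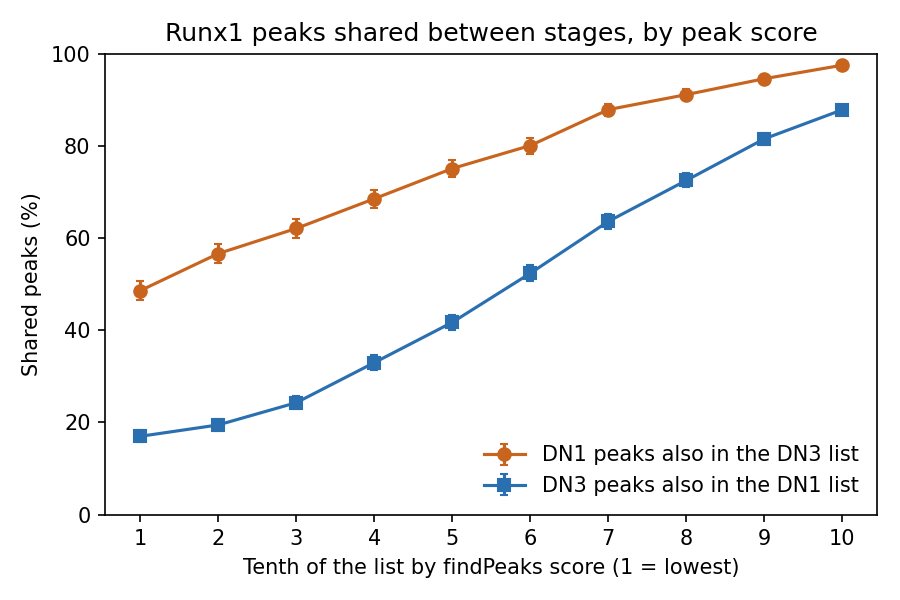
Share of Runx1 peaks that overlap a peak of the other stage's list (y axis, %), by deciles of the findPeaks score within the DN1 list (circles) and the DN3 list (squares), decile 1 holding the lowest scores. Bars are 95% Wilson intervals. The share rose from 48.6% to 97.6% over the DN1 deciles and from 17.0% to 87.9% over the DN3 deciles.

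Runx1 peaks found at both stages were the stronger peaks of each list. In DN1 cells the median findPeaks score was 199 at shared and 133 at DN1-only peaks, a log2 difference of 0.58 (95% bootstrap interval 0.56 to 0.61). In DN3 cells it was 431 at shared and 195 at DN3-only peaks, a log2 difference of 1.14 (1.12 to 1.17). Both differences had an adjusted p of 1e-05 in the permutation test, the smallest that 100000 resamples can give. Peaks are not replicates, so these p-values describe the 2 lists. Both lists are cut at a lowest tag count and lowest folds, and weak peaks are the likelier ones to miss such a cut in the other list. The direction of this difference therefore does not by itself show a difference in occupancy. The share of DN1 peaks that were shared rose in each decile of the DN1 score, from 48.6% in the lowest to 97.6% in the highest, where 52 of 2144 peaks were DN1-only. The share of DN3 peaks that were shared rose from 17.0% in the lowest decile to 87.9% in the highest, where 401 of 3312 peaks were DN3-only. In these highest deciles, 12 DN1-only and 349 DN3-only peaks lay more than 1 kb from any peak of the other list. In the upper 50% of each list by score, 1042 DN1-only and 4702 DN3-only peaks were found.

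**Figure D2:**
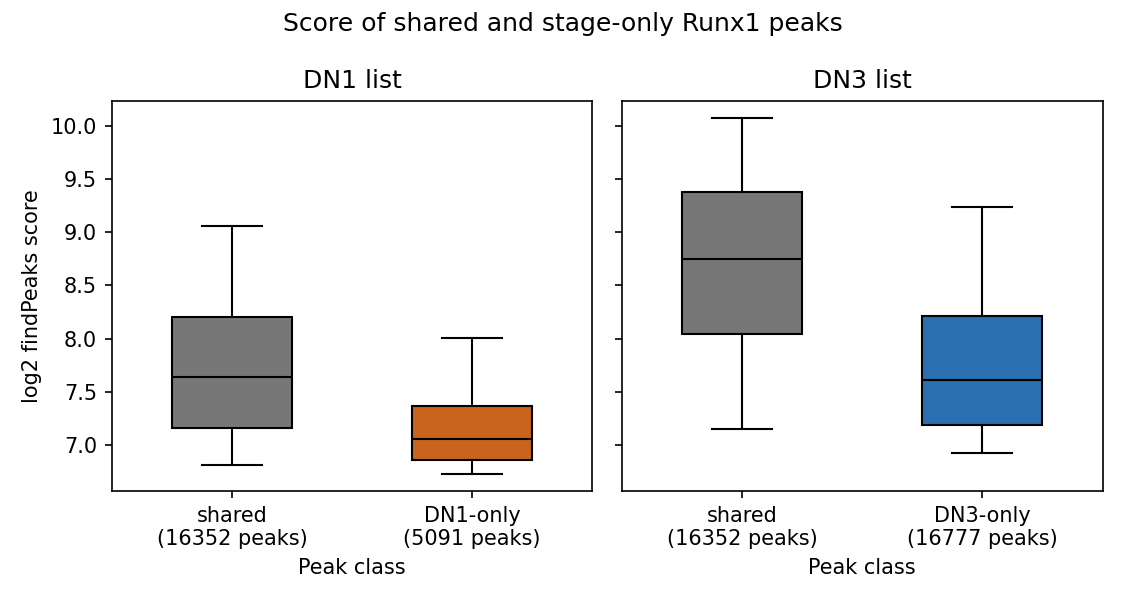
log2 findPeaks score (y axis) of shared and stage-only Runx1 peaks in the DN1 list (left) and the DN3 list (right). Boxes span the interquartile range around the median and whiskers the 5th to 95th percentile. Shared peaks score higher than stage-only peaks by 0.58 in DN1 and by 1.14 in DN3. The 2 lists have different score ranges.

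The highest-scoring DN3-only peak lay on chromosome 8 at 86135909 to 86136183. It had a score of 1489 and a fold over input of 198, and the centre of the nearest DN1 peak was 4.03 kb from its own. The DN3-only peak at 25404723 to 25404997 on chromosome 2 followed with a score of 1482 and a fold over input of 236, and its nearest DN1 peak was 259 bp away between centres. The DN3-only peak on chromosome 10 at 122195484 to 122195758 scored 1325 with a fold over input of 110, and the nearest DN1 peak was 19.2 kb away. The DN3-only peak on chromosome 9 at 123832806 to 123833080 scored 1416, but its input was 17.9 times the list's median and its fold over input was 14.2.

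The highest-scoring DN1-only peak was on chromosome 7 at 26052437 to 26052651, with a score of 749 and a fold over input of 61.3. Its nearest DN3 peak was 540 bp away between centres. Of the 5 named DN1-only peaks, 4 had a DN3 peak within 1 kb. They included a peak on chromosome 13 at 23853201 to 23853415 with a score of 713 and one on chromosome 3 at 96050687 to 96050901 with a score of 678. The exception, on chromosome 11 at 3057494 to 3057708, had a score of 713 at an input 17.4 times the list's median and a fold over input of 5.32. On chromosome 8 a named peak of each stage faced the other. The DN1-only peak at 72736523 to 72736737 scored 692 in its list and the DN3-only peak at 72736236 to 72736510 scored 1387 in its own, with centres 257 bp apart.

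The highest-scoring shared peaks of both lists included a pair near the end of the X chromosome. The peak at 166429188 to 166429402 had the top DN1 score, 1288, and 14230 tags, and the one at 166436034 to 166436248 scored 1285 with 17821 tags, the most of any DN1 peak. The overlapping DN3 peaks scored 1617 and 1653, the latter being the top DN3 score. Input at this pair was 17.2 and 17.8 times the list's median in DN1, and 3.39 and 3.29 times in DN3. Other shared peaks high in the DN3 list were those on chromosome 17 at 6429017 to 6429291 (score 1645), chromosome 6 at 113256552 to 113256826 (score 1601) and chromosome 15 at 72897904 to 72898178 (score 1586). Their folds over input were 160, 399 and 278. In the DN1 list, the shared peak on chromosome 16 at 11144109 to 11144323 scored 1085 with an input 23.3 times the median. It was followed by peaks on chromosome 17 at 56218804 to 56219018 (score 983) and on chromosome 11 at 87256674 to 87256888 (score 965), with folds over input of 54.7 and 31.9. A neighbouring chromosome 11 peak tied with the last at a score of 965 and ranked after it by normalized tag count.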

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

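Tests of repeated sequence, also by locus, and the score difference in other units were chosen after the results had been seen. The tests within strata of score and of local background were set before their results were seen.

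The difference between shared and stage-only peaks was larger in DN3 than in DN1 cells, by 0.56 on the log2 scale of the findPeaks score. It was flagged by exchanging the list labels of peaks, which is no test of the stages, since each stage has 1 list and peaks are not replicates. DN3 scores had the wider spread, with a log2 interquartile range of 1.53 against 1.00 in DN1. In units of that range the difference between shared and stage-only peaks was 0.75 in DN3 and 0.58 in DN1. By fold over input the log2 difference was larger in DN3 by 0.33. No change between the stages was concluded from these values.

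Input was not part of the comparisons, yet it carried strong signal at some Runx1 peaks. The highest scaled input was 235.8 tags in DN1 and 494.8 tags in DN3, against medians of 9.8 and 9.9. Each list had 50 peaks with input of at least 10 times its median, and they made up 19 of the 20 DN1 peaks and 14 of the 20 DN3 peaks with the most tags. On chromosome 6, 17 such DN1 peaks stood between 47605127 and 47728189, and 8 of them had a twin. The sequence of high-input peaks may be present in more copies than the reference holds. Of the shared high-input DN1 peaks, 70.5% (31 of 44, exact 95% interval 54.8% to 83.2%) matched a high-input peak in DN3, whose input libraries are separate, against 11 of 16308 other shared peaks. Tags shared between repeated copies could give such matches too, so the matches do not tell these explanations apart. The X chromosome pair did not match, with input 17.2 and 17.8 times the list's median in DN1 and 3.39 and 3.29 times in DN3. Counted by locus, with peaks up to 100 kb apart joined, 24 of 26 loci matched (exact 95% interval 74.9% to 99.1%). Any matching peak was enough for a locus to count, a looser rule than the count by peak. Tags shared between repeated copies were tested by the frequency of twins, which does not decide for high-input peaks in general. The odds ratio of 18.9 in DN1 came from the chromosome 6 locus alone, and none of the 33 high-input DN1 peaks outside it had a twin. In DN3 the twins among high-input peaks also came from 1 locus. There 7 of 8 peaks had a twin, and none of the 42 others did. No biological explanation was tested for these peaks.

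The excess of DN3-only over DN1-only peaks, 16777 against 5091, could reflect a DN1 list of lower sensitivity. DN1 peaks had the lower median folds over input and local background, although these folds are not directly comparable between the lists. The share of DN3-only peaks fell from 83.0% in the lowest score decile to 12.1% in the highest, which goes with a lower DN1 sensitivity. Loss by peak strength alone was tested by permuting shared and DN3-only status within 50 score strata. Of 23894 pairs of adjacent DN3 peaks, 56.6% had the same status, above each permutation (mean 51.4%, highest 52.7%). The DN3 score alone therefore does not account for which DN3 peaks were missing from DN1. This does not exclude a lower sensitivity at all sites, since the DN3 score may not capture all of a site's strength. Nor does the agreement of neighbours measure how many peaks were missing. In 100 joint strata of the DN3 score and the DN3 fold over local background, score classes were coarser than the 50 strata. There, 108% of the excess of same-status neighbours over permutations was left. This does not decide on the caller's filter in DN1. That filter acts on the DN1 fold over local background, which is unknown at DN3-only peaks. A lower DN1 sensitivity at all sites, a sensitivity that varies by region and a change of occupancy between the stages all remain open. Tags per library at DN3 positions were not analysed here.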

How the results depend on the processing

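No paired analysis was possible because the deposited lists hold 1 combined list per stage and no values per replicate. Leaving out single replicates, the count test per library with its normalizations, and the gene list, annotation and motif tests with their alternatives were not run for the reasons given in the processing. Alternatives named here as added were chosen after seeing the data. The shared percentage of DN1 and of DN3 peaks, 76.3% and 49.4% by the main rule, was 72.8% and 47.1% with centres within 100 bp, 73.3% and 47.4% with a reciprocal overlap of 50%, and 79.9% and 51.7% with centres within 1000 bp. With the upper 50% of each list by score it was 79.8% and 51.6%, and by normalized tag count (added) also 79.8% and 51.6%. These halved lists held 10722 DN1 and 16565 DN3 peaks by construction. At equal length it was 64.3% for both, which is one value because the overlap is one-to-one. Each list then had 7653 stage-only peaks, so equal length removes the excess of DN3-only peaks by construction. Against the whole other list, the shared percentage was 90.3% and 71.6% in the upper 50% and 97.6% and 87.9% in the upper 10% (added). Over the main rule, the 2 centre distances and the reciprocal overlap, the DN1-only peaks numbered from 4316 to 5842 and the DN3-only peaks from 15995 to 17528. Removing unplaced contigs, twins and high-input peaks (added) left 5044 DN1-only and 16644 DN3-only peaks. Chance overlap was 1.70% and 1.1% for moves of 100 kb and 2.10% and 1.36% for moves of 10 kb (added). The score difference kept its sign and p of 1e-05 under all 6 alternatives, from 0.57 to 0.62 in DN1 and from 0.90 to 1.20 in DN3, where fold over input gave the lowest value. With centres within 1000 bp, 4 of the 5 named DN1-only and 2 of the 5 named DN3-only peaks became shared, and no named peak changed class under the other overlap rules. With at least 104 tags per DN1 peak and 116 per DN3 peak, weaker sites lay below what the lists report.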

Other observations

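Tests of chance order, also up to 1 kb, the count of windows and the tests of DN1 input were chosen after a first look at the results, and tests of repeated copies and DN3 input were set before their results were seen.

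Stage-only Runx1 peaks gathered in regions of one stage. In 100 kb windows of mm9, 6 windows held 5 or more stage-only peaks that were all DN1-only, and 296 held 5 or more that were all DN3-only. Permuting the classes within chromosomes gave means of 0.490 and 214 windows and highest values of 5 and 262 (one-sided permutation p = 1e-05 for both, the smallest that 100000 permutations can give). Among the all-DN1 windows, the densest region lay on chromosome 19 between 37509231 and 37598429, with 10 DN1-only peaks and no DN3 peak in its window. Chromosome 1 between 95803327 and 95877859 and chromosome 6 between 52108280 and 52190672 each held 6 DN1-only peaks and no DN3 peak. Another 6 lay on chromosome 2 between 167939168 and 167995986, beside 2 shared peaks. The other all-DN1 windows held 5 such peaks each, on the X chromosome between 72975238 and 72996020 and on chromosome 17 between 15114803 and 15177758, beside 1 and 5 shared peaks.

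Among the all-DN3 windows, the densest region lay on chromosome 9 between 44804695 and 44884845, with 12 DN3-only peaks and 1 shared peak. Its DN3-only peaks had a median score of 299 against 195 for all DN3-only peaks. Windows with stage-only peaks of both stages were not ranked. All-DN3 windows with 10 DN3-only peaks lay on chromosome 1 (89703120 to 89799139), chromosome 6 (41005640 to 41087350), chromosome 10 (19218102 to 19298165), chromosome 11 (117104162 to 117195723), chromosome 13 (52007062 to 52099708) and chromosome 16 (91433819 to 91491452). Each also held from 1 to 5 shared peaks. On chromosome 6 the next window, 41100990 to 41178226, held 9 more. A region on chromosome 1 between 43502368 and 43599534 had 9 DN3-only peaks and no DN1 peak at all. Genes in these regions were not assigned here, and the regions were singled out after their counts were seen.

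A hypothesis, for distances over 1 kb only, is that Runx1 occupancy changes between DN1 and DN3 in part over regions. Of 13049 pairs of adjacent stage-only peaks 1 to 50 kb apart, 70.5% were of the same stage, against a mean of 64.3% and a highest value of 66.0% in 100000 permutations within chromosomes, which argues against a chance order (two-sided permutation p = 2e-05, the smallest they can give). Up to 1 kb the result went the other way: 40.6% of 759 pairs were of the same stage, against a permuted mean of 64.3% (permutation p = 2e-05). That comparison is not a fair one, since centres within 1 list were at least 371 bp (DN1) or 518 bp (DN3) apart, while DN1-only and DN3-only centres came as close as 245 bp, and the permutation ignores this. The order of the stages below 1 kb therefore stays open. Peaks marked as twins, high input or contigs are too few to account for the excess of same-stage neighbours over 1 kb. Without them 12848 of the 13049 pairs were left and 100.3% of the excess was kept. With so few pairs removed, the excess could not have fallen far. Tags shared between copies that lack these marks were not covered. A twin needs equal values in all 5 measures, and the treatment of reads with several alignments is not given. The DN3 input was not raised over the all-DN3 windows as a set. Its median at 1714 DN3-only peaks of these windows was 0.899 times the list's median (95% bootstrap interval 0.899 to 1.00), below the 1.3 set as its bound. It equalled the median at all DN3-only peaks. More DNA copies in DN3 in some of these windows stay open. Permutations gave a mean of 214 windows against 296 observed, and a median over all of them could miss copies in a part. Fewer copies in DN1 stay open too. In the 207 all-DN3 windows that hold a shared peak, the median DN1 input at 480 shared peaks was 1.00 times the list's median (0.898 to 1.00), above the bound of 0.769. Only sites still called in DN1 enter this median, so sites missing from the DN1 list were not measured. A median over all these windows could also miss a loss of copies in a part. More DNA copies in DN1 in the all-DN1 windows stay open, since the median DN1 input at their 38 DN1-only peaks was 1.1 times the list's median with an interval from 0.898 to 1.5, which includes 1.3. Enrichment that differs by region between the preparations may give the same pattern and stays open, as do the stage and the days in culture, which were not separated by the design.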
